A study of Arabidopsis thaliana with 4 samples.

How the data were processed

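Total RNA from unopened flower buds was made into libraries with a whole transcriptome kit and sequenced on a SOLiD 3+ instrument, per the labels' protocols. For each library the authors deposited a list of the distinct read sequences that could be placed on the genome, each with a count of how often it was read, its mapped length and its number of placements. A second list gave the position, strand and mismatches of every placement on the TAIR9 assembly, per the file headers and the accompanying note. The deposited counts are whole numbers per distinct sequence and are not normalized. The aligner and its settings are not given in the sources used here. Mapped lengths ran from 40 to 50 bases. The most placements of a distinct sequence were 259, 259, 266 and 336 in Col-0 replicates 1 and 2 and dcp5-1 replicates 1 and 2. Whether sequences with more placements were dropped is not given in the sources used here, and such a limit would lower the shares of repeats, 5S and other ribosomal RNA genes among them.

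Placements were assigned to genes with the RefSeq annotation of the TAIR10.1 assembly, which carries 37880 genes used here. Coordinates are given on TAIR9 as in the deposited lists. The annotation was checked against the placements by shifting it: 96.2 to 97.2% of uniquely placed nuclear reads lay in sense exons without a shift, 84.0 to 85.3% with a shift of 50 bp in either direction, and 70.5 to 71.8% with a shift of 200 bp. Reads were counted per gene over exons on the sense strand, from sequences with a single placement, each weighted by its count. A read was assigned by its middle base, and left out of the gene counts where that base lay in exons of more than 1 gene on the strand; shares of nuclear exons keep such reads. Reads with a single placement made up 49.4 and 48.5% of placed reads in Col-0 replicates 1 and 2 and 50.0 and 52.6% in dcp5-1 replicates 1 and 2, so genes with near-identical copies are counted low and their values are uncertain. Reads of the chloroplast and mitochondrial genomes were used only as shares of each library. Shares were taken over uniquely placed reads, and over all placed reads with each placement given an equal part of its read.

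Genes were compared between genotypes with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, TMM factors, filterByExpr, two-sided), on all 4 libraries with genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Of the annotated genes 19150 passed the filter. Log2 fold changes are dcp5-1 over Col-0, and their standard errors come from the same fit. CPM values are counts scaled to the TMM-adjusted library sizes. Windows of 1000 bp per strand that overlap no gene on that strand were tested in the same way, with library sizes and factors from the gene counts. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with the estimated correlation and fry beside it, adjusted over 18 lists. Ratios for genes with few reads have exact 95% intervals for counting error, and a group at 0 was set to a floor of 3 counts over the group. Shares were compared with an exact permutation test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the counting, the permutation tests with 100000 resamples, the bootstrap with 10000 draws and the plots.

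The lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The lists were processing bodies, decapping and deadenylation, small RNA silencing machinery, RNA-directed DNA methylation and DNA methylation, loci silenced by DNA methylation, microRNA targets, microRNA precursors, TAS transcripts, trans-acting siRNA targets, floral organ identity and meristem, tapetum and pollen wall, late pollen and sperm, photosynthesis, seed storage and late embryogenesis, heat shock proteins, rapidly induced and short-lived transcripts, defence, mitotic cell cycle, cytosolic ribosomal proteins, SAUR genes and transposable element genes. Named genes were DCP5, the 10 largest rises and 10 largest falls among genes that passed, had both libraries of one genotype above both of the other and a mean of at least 5 CPM in the higher genotype, up to 4 members of each list with the smallest p and any other member that passed, all TAS transcripts with ARF2, ARF3 and ARF4, and the processing body list. The text names a part of these; a single gene among them is not reported here. Genes whose exons overlap another gene on the same strand are uncertain, among them DCL2 with 9.65% of its exon bases shared and AT1G51670 with 11.2%.

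Other settings fixed in advance were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0 and limma-voom as tests, fractional placements, each distinct sequence counted once, both strands, whole gene bodies, a replicate block, leaving out each library, and windows of 500 bp. Settings chosen after seeing the data were removal of the length trend with a spline of 4 degrees of freedom, an assumed biological coefficient of variation of 0.2, a fold of at least 2, and leaving out snoRNA and snRNA genes.

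The gene test was checked on simulated data made from the real means and library sizes for dcp5-1 against Col-0. At a biological coefficient of variation of 0.03 over 19100 genes it recovered 73.7% of genes changed 1.5-fold, 84.5% of those changed 2-fold and 98.5% of those changed 4-fold, with 13 false calls. At 0.2 over 19090 genes it recovered 0, 22.2 and 88.7%, with 3 false calls. Over 431 simulated windows 87.2% of 39 changed 4-fold were recovered. A simulated list moved 1.5-fold among 21 lists had a camera adjusted p of 2.91e-22 and an adjusted p of 0.174 with an estimated correlation.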

Results

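RNA was sequenced from unopened flower buds of Arabidopsis thaliana, from wild-type plants of the accession Col-0 and from plants carrying the mutant allele dcp5-1 in the same background. Plants grew on soil under 16 h of light and 8 h of dark. Each genotype was represented by 2 libraries of total RNA, so that ribosomal, organellar and small nuclear RNAs were sequenced alongside mRNA. The libraries held 14718413 and 18460319 placed reads for Col-0 replicates 1 and 2, and 18809983 and 17746387 for dcp5-1 replicates 1 and 2. Uniquely placed reads assigned to a single nuclear gene on its sense strand, the basis of the gene test, numbered 4391929, 5372804, 6264806 and 6220358 in the same order. The labels do not say that the libraries of a genotype came from separate plants, so p-values here measure the spread between these samples, which may be technical. That spread was small: the common biological coefficient of variation was 0.0272, and counts of the 2 Col-0 libraries gave a chi-square of 1.07 per degree of freedom, against 15.6 between the first libraries of the genotypes. The Col-0 pair still differed by slightly more than sampling noise (chi-square p = 3.27e-11), and the dcp5-1 pair by more, at 1.38 per degree of freedom. Such an excess does not show that the libraries came from separate plants. Each library was nevertheless counted as its own replicate.

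DCP5 encodes a protein of processing bodies, the cytoplasmic granules in which mRNAs are decapped and held untranslated. Its transcript (AT1G26110, chromosome 1, 9024341 to 9027955 on the minus strand, TAIR9 coordinates) was lower in both mutant libraries. Reads on its exons numbered 560 and 706 in Col-0 and 296 and 259 in dcp5-1. This corresponded to 130 ± 2.70 CPM (reads scaled to library size) in Col-0 and 44.4 ± 4.26 in dcp5-1 (SD, n = 2), a log2 fold change of -1.55 (SE 0.0762, adjusted p = 5.37e-42). The loss was uneven along the gene. The annotated 3′ UTR, from 9024341 to 9024615, held 45 and 43 reads in Col-0 and 1 and 0 reads in dcp5-1. The exons of the coding part, from 9024616 to 9027556, held 496 and 639 reads in Col-0 and 286 and 251 in dcp5-1. The mutant libraries therefore carried DCP5 reads over the coding part, at a lower level, and almost none over the 3′ UTR.

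**Figure D1:**
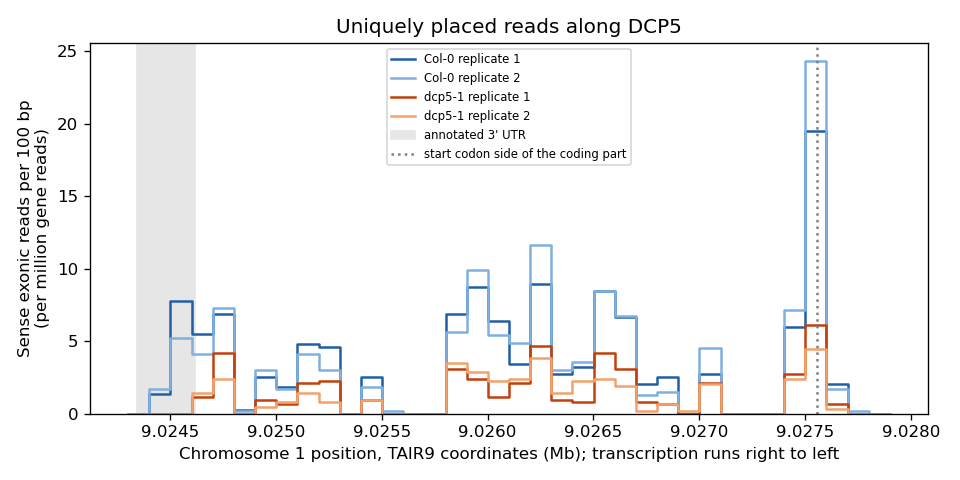
Sense-strand exonic reads along DCP5 in bins of 100 bp, scaled to the gene reads of the library, for each of the 4 libraries, against position on chromosome 1 in Mb (TAIR9), with transcription from right to left. The grey area marks the annotated 3′ UTR, where the dcp5-1 libraries held 1 and 0 reads, and the dotted line marks the end of the coding part next to the 5′ UTR.

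Across the nuclear genes the comparison asked which transcripts differ in buds when DCP5 is mutated, a protein that the series title ties to silencing by small RNAs. Among the genes that rose were PR2, a beta-1,3-glucanase induced in defence, PCC1, a gene named for its control by pathogens and the circadian clock, and the peroxidase gene PRXCB. Among those that fell were ERF104, a transcription factor of the ethylene response family, AT2G33830, annotated as dormancy and auxin associated, and several small nucleolar RNAs. Of 19150 genes tested, 6684 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 3337 of them higher and 3347 lower in dcp5-1. A fold of at least 2 was reached by 931 of these, of which 276 were higher and 655 lower. The number of calls depended on the small spread between libraries: with a biological coefficient of variation of 0.2 assumed in its place, an alternative chosen after seeing the data, 556 genes passed, 127 higher and 429 lower, and 145 of the 179 calls among the named genes other than DCP5 were lost. DESeq2 called 2644 genes of the 18036 for which it gave an adjusted p.

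The largest rises were at loci with few or no reads in Col-0. The pseudogene AT2G11410 (chromosome 2, 4543932 to 4547916) held 0 and 0 reads in Col-0 and 96 and 115 in dcp5-1. Against a floor of 3 counts over the group this was 54.7-fold higher. The exact 95% counting interval of the ratio, from the reads of both genotypes, had a lower end of 44.1-fold. The transcribed pseudogene AT4G08093 (chromosome 4, 4990153 to 4991601) held 0 and 0 reads in Col-0 and 35 and 39 in dcp5-1. By the same floor it was 19.2-fold higher, with a lower end of 15.2-fold for that interval. AT1G64795 rose from 1 and 4 reads to 155 and 113, a ratio of 41.7 with a 95% counting interval from 17.63 to 129; its fitted log2 fold change was 5.32, and 6.42 without Col-0 replicate 2. The pseudogene AT3G50625 rose from 1 and 1 reads to 26 and 39, a ratio of 25.3 with an interval from 6.72 to 213. Such intervals and floors cover counting error alone.

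Among the other rises, PCC1 went from 0.999 ± 0.440 to 9.85 ± 0.130 CPM (SD, n = 2), a log2 fold change of 3.23 (SE 0.351, adjusted p = 1.17e-14). PR2 rose from 1.54 ± 1.39 to 11.8 ± 0.926, a change of 3.02 (SE 0.316, adjusted p = 3.04e-15). Both genes had low values in Col-0. The size of the PR2 change depended on the Col-0 libraries: it was 4.35 without Col-0 replicate 1 and 2.22 without Col-0 replicate 2. PRXCB rose from 26.3 ± 0.695 to 107 ± 0.163, a change of 2.03 (SE 0.0907, adjusted p = 3.27e-46), and the glycine-rich protein gene GRP-3 changed by a similar 2.00 on the log2 scale. MLP43, of the major latex protein family, rose by 2.74 and the receptor-like kinase gene AT2G19130 by 2.40. The largest fall was that of AT5G12470, from 49.8 ± 1.27 to 4.88 ± 0.784 CPM, a log2 fold change of -3.34 (SE 0.155, adjusted p = 1.47e-44). AT2G33830 changed by -2.93 and ERF104 by -2.33, with adjusted p values of 1.70e-16 and 4.23e-13. The small nucleolar RNA genes AT2G08725, AT2G20721, AT1G08347 and AT5G02675 changed by -2.56, -2.54, -2.51 and -2.50. AT1G70185, annotated as a noncoding RNA, and AT2G35765 completed the 10 largest falls together with RR3.

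The value of RR3, which encodes a type-A response regulator of cytokinin signalling, is uncertain. Its fitted change was -2.42 (SE 0.191, adjusted p = 0.0118), but between 99.5 and 99.9% of its reads in each library lay in the stretch from 17224503 to 17224801 of chromosome 2, opposite an annotated long noncoding RNA. Elsewhere on the gene there were 118 and 146 reads in Col-0 and 119 and 132 in dcp5-1. Without Col-0 replicate 1 the fitted change was -2.42 and its adjusted p 0.210, and without Col-0 replicate 2 they were -2.43 and 0.218.

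Genes of the machinery to which DCP5 belongs changed in both directions, about as often as tested genes in general. Of 22 tested genes for processing bodies, decapping and deadenylation, 5 rose and 3 fell, with DCP5 itself among the latter, and 14 did not pass. Over all genes, 6684 of 19150 passed, a similar share. In DESeq2, 3 of the 5 rises and 1 of the 3 falls lost the call. Adjusted over the list alone, 5 rose and 4 fell. VCS, the scaffold of the decapping complex, rose by 0.56 (SE 0.0622, adjusted p = 2.72e-14) and the DEAD-box helicase gene RH12 rose by 0.38. CAF1A, a deadenylase of the CCR4-NOT complex, fell from 10.98 ± 0.619 to 2.96 ± 0.108 CPM (SD, n = 2), a log2 fold change of -1.89. The decapping enzyme gene DCP2 had a value of 0.15 and the exonuclease gene XRN4 one of -0.05, neither passing. The list as a whole did not stand apart from other genes in limma's camera test (adjusted p = 0.653). Its median of 0.12 and mean of -0.08 differ in sign, and the direction given by the test was up. Camera with an estimated correlation, used below, missed a simulated list moved 1.5-fold (adjusted p = 0.174). Failing it therefore cannot decide whether a list moved.

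Small RNA pathways were the subject named in the series title. Of 24 tested genes for the small RNA machinery, 6 rose and 3 fell, the same numbers as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.166). That share of calls is also close to the 6684 of 19150 over all tested genes. AGO10 and AGO7, which encode Argonaute proteins, rose by 0.55 and 0.60. DCL1, the Dicer-like enzyme of microRNA production, fell by 0.32, and DCL4, which makes trans-acting siRNAs, rose by 0.37. With the length trend described below removed, the adjusted p of DCL4 was 0.244. Among 18 genes for RNA-directed DNA methylation and DNA methylation, 7 rose and 1 fell, also when adjusted over the list alone. NRPD2, the shared second-largest subunit of RNA polymerases IV and V, rose from 88.9 ± 1.599 to 164 ± 1.75 CPM, a log2 fold change of 0.88, and the DNA demethylase gene DME rose by 0.56, whereas the demethylase gene ROS1 fell by 0.30. This list passed camera (adjusted p = 0.0403), but not with an estimated correlation (adjusted p = 0.493 with an estimated correlation), and its adjusted p was 0.611 with the length trend removed, 0.0558 with a replicate block, 0.0998 without Col-0 replicate 1 and 0.0910 without dcp5-1 replicate 2.

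The transcripts that small RNAs are made from, or act on, showed few changes in a common direction. Of 6 tested TAS transcripts, the precursors of trans-acting siRNAs, TAS2 fell by 0.57 (SE 0.153, adjusted p = 0.00149), with the same single call when adjusted over the list alone. DESeq2 gave TAS2 an adjusted p of 0.123, and without Col-0 replicate 2 it was 0.0665. TAS1A, TAS1C, TAS1B, TAS3 and TAS3B had values of -0.52, -0.47, -0.04, 0.17 and 0.05 and did not pass, and TAS3C and TAS4 had too few reads to be tested. The list had a camera adjusted p of 0.330. Of 20 tested targets of trans-acting siRNAs, 2 rose and 3 fell, as when adjusted over the list alone (camera adjusted p = 0.248). The auxin response factor genes ARF2 and ARF4 rose by 0.46 and 0.43, ARF3 had a value of -0.19 (adjusted p = 0.0843), and the pentatricopeptide repeat genes AT1G12300 and AT1G63080 fell by 0.92 and 0.84, with adjusted p values of 0.0915 and 0.168 in DESeq2. Of 74 tested microRNA targets, 22 rose and 13 fell, and 23 rose and 14 fell when adjusted over the list alone (camera adjusted p = 0.653). In DESeq2, 21 of the 22 rises and 12 of the 13 falls lost the call. With the assumed coefficient of variation of 0.2 all of them did. NF-YA2 rose by 0.79, ATHB-15 rose by 0.33 and AFB1 fell by 0.47, none of them called by DESeq2 (adjusted p = 0.0802, 0.0800 and 0.119). Without Col-0 replicate 2 the adjusted p was 0.0792 for NF-YA2 and 0.126 for ATHB-15. The list of 9 microRNA precursors with enough reads did not pass (camera adjusted p = 0.181). Of these 9, 3 fell, also when adjusted over the list alone, and all 3 lost the call in DESeq2. MIR168a was among the latter, with a change of -1.63 that had an adjusted p of 0.0713 in DESeq2 and 0.0621 without Col-0 replicate 1.

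Few reads came from FWA and SDC, loci kept silent by DNA methylation. FWA, an imprinted homeobox gene silent in most wild-type tissues, held 0 and 1 reads in Col-0 and 6 and 7 in dcp5-1, a ratio of 10.1 with a 95% counting interval from 1.52 to 429, and was too low to be tested. SDC held 2 and 2 reads in Col-0 and 8 and 2 in dcp5-1 and was not tested either. QQS had a value of -0.07 (adjusted p = 0.922). Of 8 tested transposable element genes, SADHU1-3 and SADHU1-1 fell by 0.78 and 0.41 and the others did not pass, with the same 2 calls over the list alone (camera adjusted p = 0.704); DESeq2 gave SADHU1-1 an adjusted p of 0.0572. The median of that list was 0.02 and its mean -0.04, and the direction given by the test was down. None of the 12 seed storage and late embryogenesis genes had enough reads to be tested.

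Of the lists tested, markers of pollen had the smallest camera p. Of 23 tested genes of late pollen and sperm, 19 fell, none rose and 4 did not pass, with a median log2 fold change of -0.99. Adjusted over the list alone, 20 fell. The members GCS1 and GEX2 had too few reads to be tested. GCS1 held 4 and 3 reads in Col-0 and 11 and 6 in dcp5-1, and GEX2 held 1 and 0 in Col-0 and 3 and 3 in dcp5-1. VGD1, a pectin methylesterase of the pollen tube, fell from 538 ± 11.1 to 254 ± 2.07 CPM (SD, n = 2), a change of -1.08 (SE 0.0432, adjusted p = 1.67e-51). Its neighbour VGDH1 fell by 1.38, the pollen pectin methylesterase gene PPME1 by 0.82, and RALF19, a peptide signal of the pollen tube, by 1.55. VGD1 and VGDH1 are close in sequence, so reads placed in both were left out of their values. The list passed camera (adjusted p = 5.61e-10) but not with an estimated correlation (adjusted p = 0.493 with an estimated correlation). Genes of the tapetum and pollen wall, active earlier in anther development, did not move as a group: 3 of 19 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.975). A6 rose by 0.29 and RPG1 fell by 0.84.

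Among 18 tested genes of floral organ identity and the meristem, 4 rose and 5 fell, and 5 rose and 6 fell when adjusted over the list alone (camera adjusted p = 0.602). AP3, which specifies petals and stamens, rose by 0.42, and SEP2 fell by 0.28. Of 12 genes of the mitotic cell cycle, 7 rose and none fell, also over the list alone, with a median of 0.32. In DESeq2, 4 of the 7 rises lost the call, and all 7 did with the assumed coefficient of variation of 0.2. The cytokinesis kinesin gene HIK rose by 0.81, the mitotic kinase gene CDKB2;1 by 0.51 and the cytokinesis syntaxin gene KN by 0.32, the last with an adjusted p of 0.0515 without dcp5-1 replicate 2. That list passed camera (adjusted p = 0.00442), but not with an estimated correlation (adjusted p = 0.493 with an estimated correlation). Of 19 photosynthesis genes of green tissue, 13 fell and 3 rose, also over the list alone, with a median of -0.25. LHCA3 fell from 1504 ± 10.2 to 1052 ± 22.6 CPM, a change of -0.52, and LHCA4 fell by 0.48, whereas the Rubisco activase gene RCA rose by 0.12, with adjusted p values of 0.0654 in DESeq2, 0.507 with each distinct sequence counted once and 0.139 without Col-0 replicate 2. The photosynthesis list passed camera (adjusted p = 0.0163), but not with an estimated correlation (adjusted p = 0.667 with an estimated correlation), and its adjusted p was 0.0743 without Col-0 replicate 1 and 0.0637 without dcp5-1 replicate 2.

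Stress-related groups went different ways. Of 18 tested rapidly induced, short-lived transcripts, 9 fell and none rose, and 11 fell when adjusted over the list alone, with a median of -0.44. In DESeq2, 5 of the 9 falls lost the call, and 6 did with the assumed coefficient of variation. TCH4, a touch-induced cell wall enzyme, fell from 53.5 ± 3.44 to 24.3 ± 0.639 CPM, a change of -1.14, and the zinc finger gene ZAT12 fell by 1.34. The list passed camera (adjusted p = 0.000890), but not with an estimated correlation (adjusted p = 0.493 with an estimated correlation). Of 6 tested heat shock genes, 3 rose and none fell, as over the list alone, with a median of 0.56. The chaperone genes HSP70-4 and HSP90-1 rose by 1.29 and 0.67. Heat shock genes passed camera (adjusted p = 0.0181), but not with an estimated correlation (adjusted p = 0.493 with an estimated correlation), nor without a filter on low counts (adjusted p = 0.0936). Of 9 tested defence genes, 3 rose and 4 fell, and 4 rose and 4 fell when adjusted over the list alone (camera adjusted p = 0.975). Besides the rise of PR2 given above, VSP1 rose by 0.30, and the transcription factor gene WRKY70 and the thionin gene THI2.1 fell by 0.97 and 0.68.

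Of 16 cytosolic ribosomal protein genes, 11 rose and 2 fell, also over the list alone, with a median of 0.14. RPS6A and RPL4A rose by 0.45 and 0.44, and RPS18A fell by 0.89. With each distinct sequence counted once, 7 of the 11 rises were lost and the list had a camera adjusted p of 0.339, and 5 of the rises were lost in DESeq2, 5 without Col-0 replicate 2 and all 11 with the assumed coefficient of variation of 0.2. These genes have close paralogs and their values rest on reads with a single placement, so they are uncertain. The list did not pass camera (adjusted p = 0.0890, and adjusted p = 0.493 with an estimated correlation), and passed camera at the preset correlation once the length trend was removed (adjusted p = 0.0243). Of 10 tested SAUR genes, a family of small auxin-induced genes, 2 fell, and 1 when adjusted over the list alone (camera adjusted p = 0.411). SAUR26 had a change of -1.14, but of -0.33 without Col-0 replicate 2 (adjusted p = 0.747), and it was not called by DESeq2 (adjusted p = 0.272) or without dcp5-1 replicate 2 (adjusted p = 0.118). Across 18453 protein-coding genes the log2 fold change rose with exon length (Spearman rho 0.149 across genes, which are not independent replicates), which is the length trend named above. Coverage along genes differed too: with the exon models of longer genes split into 3 equal parts, the 5′ part held a share of the reads in both outer parts of 0.480 and 0.480 in Col-0 and 0.503 and 0.499 in dcp5-1.

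**Figure D2:**
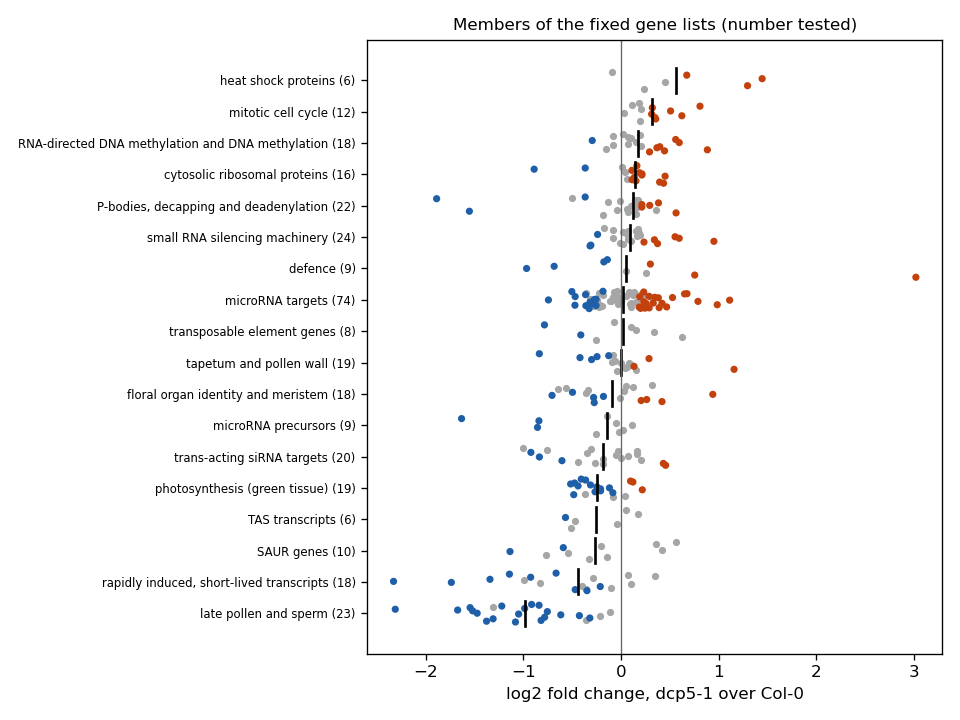
Log2 fold changes (dcp5-1 over Col-0) of the tested members of each gene list, 1 dot per gene, with lists ordered by their median (black bar) and the number tested beside each name. Red and blue dots passed an adjusted p of 0.05 in edgeR as higher and lower, and grey dots did not; the late pollen list has the lowest median, -0.99.

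Outside annotated genes, the comparison asked whether reads arose or were lost in windows with no gene on their strand. They were not chosen for repeats or for silencing. Windows that rose lay mostly between genes, many of them at copies of the 5S ribosomal RNA gene, and windows that fell lay both between genes and opposite them. Of 420 windows of 1000 bp per strand with enough uniquely placed reads, 24 rose and 47 fell in edgeR's test. Between genes 17 of 67 rose and 10 fell, and opposite a gene 7 of 353 rose and 37 fell. Of the 24 that rose, 13 overlapped a 5S copy, as did 16 of the tested windows. A window between genes, from 3055001 to 3056000 on the plus strand of chromosome 4, was singled out after its values were seen. It lies between the first and last 5S copies found on that chromosome (3054703 to 3061265). This window held 50 and 47 reads in Col-0 and 172 and 235 in dcp5-1. Its log2 fold change was 1.70 (SE 0.189, adjusted p = 3.72e-08). These calls depended strongly on the libraries: 3 windows passed with a replicate block, all of them lower and none higher, and 0 passed in edgeR without Col-0 replicate 1 or without Col-0 replicate 2, where 76 and 70 windows had an unadjusted p under 0.05. DESeq2 called 18 windows on all libraries, and 348 passed in edgeR, 229 higher and 119 lower, when reads with several placements were shared among them; 143 of those 229 overlapped a 5S copy.

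The make-up of the libraries differed between genotypes as well. Sense exons of nuclear genes took 62.7% ± 0.248 of uniquely placed reads in Col-0 and 67.6% ± 0.0969 in dcp5-1 (SD, n = 2), a difference of 4.82 percentage points. The chloroplast genome took 20.9% ± 0.138 in Col-0 and 18.4% ± 0.361 in dcp5-1, and the mitochondrial genome 12.1% ± 0.0856 and 10.4% ± 0.242. Reads antisense to nuclear genes took 0.559% ± 0.00849 in Col-0 and 0.395% ± 0.0184 in dcp5-1. In each of these parts the libraries of one genotype lay wholly apart from those of the other, and the two-sided exact permutation p was 0.333, the smallest that 2 libraries against 2 allow. Ribosomal RNA repeats, whose reads mostly have several placements, took 30.1% ± 0.446 of placed reads in Col-0 and 30.4% ± 1.56 in dcp5-1 when each read was shared among its placements, a difference smaller than the spread between the mutant libraries (exact permutation p = 1.0). Among uniquely placed reads their share went the other way, 1.81% ± 0.00141 in Col-0 and 1.69% ± 0.0354 in dcp5-1 (exact permutation p = 0.333). Nuclear reads outside genes also turned direction, from 0.526% ± 0.00495 in Col-0 and 0.379% ± 0.00919 in dcp5-1 among uniquely placed reads to 1.25% ± 0.00566 and 2.03% ± 0.0120 with reads shared among placements. The class of ribosomal RNA repeats was limited to the larger repeats, so 5S copies between genes and outside those repeats counted as reads outside genes. Of 345 windows between genes tested with shared reads, 154 overlapped a 5S copy. The 5S copies took 0.350% of placed reads in Col-0 and 0.811% in dcp5-1. With reads shared among placements, the chloroplast took 25.6% in Col-0 and 21.5% in dcp5-1 and the mitochondrion 8.64% and 7.82%. Their differences were -4.09 and -0.82 percentage points on that count, against -2.51 and -1.68 among uniquely placed reads.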

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

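The comparison of 5S ribosomal RNA reads was chosen only after the result was seen. Reads with several placements, which the gene test leaves out, held a signal that differed between the genotypes. Copies of the 5S ribosomal RNA gene on chromosomes 3, 4 and 5 took 0.359 and 0.342% of placed reads in Col-0 and 0.824 and 0.798% in dcp5-1. The mean share was 0.350% ± 0.0120 in Col-0 and 0.811% ± 0.0184 in dcp5-1 (SD, n = 2), a ratio of 2.32. Shares of repeated genes hold for the reads as placed, since any limit on the placements of a read is not given in the sources used here. All of these reads lay on the sense strand of the copies.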

How the results depend on the processing

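Removal of the length trend, the assumed coefficient of variation of 0.2, the fold of at least 2 and the fits without snoRNA and snRNA genes were chosen only after the result was seen. DCP5 kept its direction and its call under all 16 alternatives run for it, from -1.65 to -1.44, with a largest adjusted p of 9.10e-05; leaving out single libraries gave -1.65 to -1.46. The 6684 changed genes became 2644 with DESeq2, 556 with the assumed coefficient of variation and 931 with a fold of at least 2, and 4601 to 5676 when single libraries were left out. The assumed spread is wider and the fold limit keeps fewer genes by construction; for DESeq2 the cause was not tested. The 71 changed windows became 22 without a filter, 18 with DESeq2, 348 with fractional placements, 39 with the assumed coefficient of variation and 56 with a fold of at least 2, and 0 to 45 without single libraries; the cause was not tested. With a replicate block, 6765 genes and 3 windows passed, the windows all lower. Across 11317 genes, the differences between replicates 1 and 2 of the genotypes had a correlation of -0.0176, so the numbers were not taken to pair the libraries. The 6 lists that passed camera became 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05, and 4 to 6 without single libraries. Camera with an estimated correlation also missed a simulated list moved 1.5-fold (adjusted p = 0.174), so its failures decide nothing about the lists. The simulated genes varied independently, so the simulation does not secure the passes at the preset correlation of 0.01 either. Estimated correlations were 0.458 for photosynthesis, 0.144 for the mitotic cell cycle and 0.0926 for DNA methylation. They were 0.0418 for late pollen, 0.0411 for rapidly induced transcripts and -0.109 for heat shock. By fry 4 lists passed: late pollen, heat shock, rapidly induced transcripts and ribosomal proteins, the last of which had not passed camera. The difference in the share of nuclear sense exons, 4.82 percentage points, was 5.42 with each distinct sequence counted once and 3.97 with fractional placements, and 4.65 to 4.998 without single libraries. Of 205 named genes besides DCP5, 179 passed; 150 of these lost the call under at least 1 alternative, 145 of them with the assumed coefficient of variation, and 108 lost it under some other alternative. Changes of sign, whose cause was not tested, were mostly at genes that did not pass. With each distinct sequence counted once, RPL23AA (0.14 otherwise) had -0.056, LHCB2.1 (0.22 otherwise) -0.026, TAS1B 0.041 and XRN4 0.0062, and LHCB2.1 had -0.048 with fractional placements. QQS had 0.0009 over the whole gene body, and TAS3B -0.0065 with limma-voom. With the length trend removed QQS had 0.10, MIR2112 0.0088, TAS1B 0.081 and VCR -0.12. Without single libraries QQS ran from -0.23 to 0.065, MIR2112 from -0.65 to 0.052, TAS1B from -0.26 to 0.15, TAS3B from -0.43 to 0.41, VCR from -0.027 to 0.16, XRN4 from -0.12 to 0.028 and LSM1A from -0.16 to 0.25. Lists that did not pass turned direction at these camera adjusted p values: defence at 0.993 with DESeq2, 0.911 with both strands, 0.963 with the length trend removed and 0.997 without snoRNA and snRNA genes; processing bodies at 0.959 with the length trend removed; tapetum at 0.958 with fractional placements, 0.996 over gene bodies, 0.978 with a replicate block and 0.959 with the length trend removed; transposable element genes at 0.667 without a filter. Direction also turned for defence, tapetum, SAUR and transposable element genes without dcp5-1 replicate 2, and for tapetum without Col-0 replicate 2. Without single libraries their adjusted p ran from 0.301 to 0.942 for defence, 0.544 to 0.887 for tapetum, 0.114 to 0.963 for SAUR genes and 0.156 to 0.866 for transposable element genes. In simulated data 84.5% of 2-fold changes were recovered at a spread of 0.03 and 22.2% at 0.2, at the same depth; what depth limits was not tested apart from spread.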

Other observations

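Tests of the scaling, of the length trend in the 3 patterns and of younger buds were chosen only after the result was seen, as were the groups by RNA class and the clock genes; the tests of loss of short RNAs and of the time of day on clock genes not looked at before were not. Small stable RNAs of the nucleus were lower in dcp5-1. Of 177 tested snoRNA genes, which guide chemical modification of ribosomal RNA, 137 fell and 4 rose, with a median log2 fold change of -0.82. All 11 tested snRNA genes, which encode RNAs of the spliceosome, fell, with a median of -1.38. Among 185 long noncoding RNA genes 51 fell and 1 rose, with a median of -0.33. Reads antisense to genes fell at 42 and rose at 5 of 433 genes tested, with a median of -0.24 and a Spearman rho of 0.118 with the sense change across genes.

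Genes of the circadian clock, a list written after some of its members had been seen, changed in both directions. Of 9 dawn-phased genes 4 rose and 1 fell, with a median of 0.15, and of 10 later-phased genes none rose and 4 fell, with a median of -0.29. The dawn transcription factor genes LHY, CCA1 and RVE8, all seen before the list was written, rose by 1.18, 0.43 and 0.42. PRR5, FKF1, PRR9 and PRR7, active later in the day, fell by 1.40, 1.22, 0.49 and 0.35. Of these, FKF1 alone had not been seen before.

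The fall of snoRNA and snRNA genes was set against 2 technical explanations. The tables argue against scaling to nuclear mRNA, whose share was higher in dcp5-1, as the whole cause: counted against all placed reads, the median of the 188 genes was still -0.65, with quartiles of -1.11 and -0.28. A loss of short RNAs in library preparation could not be decided, since the change had a Spearman rho of -0.0216 with gene length (95% bootstrap interval -0.164 to 0.118, permutation p = 0.769), and a loss of all short RNAs alike may leave no trend among them. Removing the length trend of protein-coding genes, whose shortest decile had a median of -0.10, moved the median from -0.86 to -0.59, while 5S ribosomal RNA, from copies of 120 bp, was 2.32 times as high in dcp5-1; neither value settles the point. An effect of the genotype stays open as a hypothesis that was not tested.

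The fall of late pollen genes remained when the length trend was removed, with a median of -0.93 and quartiles of -1.36 and -0.65, which argues against that trend as the whole cause. Younger buds in the mutant sample are a hypothesis made from these values: the median of the tapetum list, expressed before pollen matures, lay 0.99 above that of the late pollen list. Both medians were known when the comparison was chosen, so it is no independent test. A direct effect of the genotype on pollen would give the same difference, and these explanations cannot be told apart here.

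For the clock genes, the hypothesis of a different time of day at harvest could not be decided. Among 9 genes not looked at before, 6 dawn-phased and 3 later-phased, the medians were 0.049 and -0.29. They differed by 0.34 (95% bootstrap interval 0.16 to 1.37, exact permutation p = 0.0833), and the genes were few. Of the 6 dawn-phased genes LNK1 rose by 0.22, LNK2 fell by 0.14 and the others did not pass. FKF1 alone passed among the 3 later-phased ones. A trend with transcript length is argued against by the difference of 0.57 over all 19 clock genes once that trend was removed (interval 0.24 to 0.97). The labels used here give no harvest time, and an effect of the genotype on the clock stays open, untested.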
